A study of Drosophila melanogaster with 3 samples.

How the data were processed

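Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed from transgenic fruit flies that carry svp, an orphan nuclear receptor of the COUP-TF family, fused to enhanced GFP. Per the labels, an anti-GFP antibody was used on chromatin of whole animals of both sexes at the white prepupa stage, the start of metamorphosis, after sonication. The 3 samples are biological replicates of 1 group, with the replicate numbers taken from the labels. No control library is among the samples used here, so no comparison between groups was possible.

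The files are peak lists in narrowPeak format on the dm6 and dm3 builds. Per the deposited manifests, each replicate's list was made from that replicate's alignments and 1 control file, which was the same for all 3 replicates of a build. A pooled list was made from the alignments of all 3 replicates, and an IDR-thresholded list (irreproducible discovery rate, labelled optimal) from the replicate and pooled lists. The aligner, the peak caller, the number of reads and the IDR threshold are not given in the sources used here. Each replicate and pooled list holds exactly 30000 peaks, so the number of peaks in them says nothing about the samples. Sequencing depth per sample is therefore unknown, and the intervals given cover counting error over peaks only.

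The signal value of each peak is the authors' deposited value, with no statement of its scaling, and was used only to rank and describe peaks within 1 list. The −log10 q-value of each peak is also as deposited by the authors and was not tested further. The summit, a position within each peak per the file columns, was used as the location of the peak. Where 1 interval carried several summits, as 46 intervals of the dm6 IDR-thresholded list on the main chromosomes did, each summit was counted. All coordinates are on dm6, counted from 1. They were used with the RefSeq sequence of release 6 of the Drosophila melanogaster genome and the Ensembl 115 annotation (FlyBase release 6.54) after checking that no peak passed the end of an arm. The dm3 lists served only for counts, overlaps between lists and replicate support, since no dm3 sequence or annotation was used here, and nothing was converted between builds.

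Replicates were compared by the top 5000 peaks of each list by signal value, and a peak counted as shared where its summit lay inside a peak of the other list. The overlap was set against 1000 seeded random placements within each chromosome, one-sided, for which the smallest p is 0.001. An IDR-thresholded peak was called supported by a replicate where its summit lay inside one of that replicate's top 5000 peaks. Summits on the chromosome arms were assigned to the first matching class among promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, CDS, 3' UTR, other exon, intron and intergenic. Each class was tested two-sided against 1000 placements, and each arm by a two-sided exact binomial test against its share of length. A total of 18 motifs, and then every 8-mer with both strands as 1, were tested for presence within 50 bp of the summit against a window of the same size centred 500 bp to a random side. This used a two-sided exact McNemar test. The half-site and the other short motifs needed an exact match, and the direct and inverted repeats allowed 1 mismatch. A reversed, not complemented, DR1 was the negative control. Genes with a summit within 1000 bp of a TSS were counted in 35 gene lists against all other protein-coding genes of the arms by a two-sided Fisher's exact test. Benjamini-Hochberg adjustment was made within each family of tests, with a threshold of 0.05. Each list was also set against 10000 random lists matched on gene length and number of TSSs. Of the list symbols, 2 matched no gene and were left out. Means ± SD over replicates were computed from the top 5000 peaks of each replicate, and intervals of shares are exact 95% binomial intervals.

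Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The steps were tested on simulated data. Of 1500 summits placed near a TSS, 100% were returned as promoter summits, and of 200 DR1 sites placed in summit windows, 100% were found. With 11 members of the glycolysis list set to carry a peak, that list and no other of the 35 was called. Of simulated peaks, 69.3% were copied into a second list and 69.9% were found shared.

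The tests, gene lists, motifs and the rule for named genes were fixed before the data were examined. The text names svp, the gene with the nearest TSS to each of the 20 highest IDR-thresholded peaks supported by all 3 replicates, up to 4 members of each gene list with the highest promoter peaks and up to 2 of those without one in alphabetical order, and the 5 genes with the most summits in their body. The lists covered nuclear receptors, ecdysone response, ecdysteroid synthesis, metabolic pathways, signalling pathways, cell types of the prepupa and large gene families. Alternatives changed the overlap rule, the number of top peaks, the peak set, the TSS distance, the motif window and control, the background of the gene lists, the build and each replicate. Peaks on the mitochondrial genome were left out of the arm, motif and gene analyses.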

Results

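Anti-GFP ChIP-seq of GFP-tagged svp, a COUP-TF family nuclear receptor, was done in whole white prepupae, in 3 biological replicates. No GFP-free sample is used here, so svp binding cannot be told apart from open chromatin taken up by any antibody. The labels name 1 group, so the data answer where anti-GFP peaks lay along the genome and how far the replicates shared those places. The combined IDR-thresholded list held 5443 peaks on dm6 with a median width of 456 bp, covering 2.05 Mb, and 6656 peaks on dm3. Signal values in the dm6 list ran from 120 to 3228, with a median of 219. The replicate lists of 30000 peaks had median signal values of 18.4, 20.4 and 14.9, and maxima of 1146, 1407 and 1064. Read depth is unknown.

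The highest peaks lay at promoters and introns and were found in every replicate. Of the 20 highest peaks supported by the top 5000 of all 3 replicates, 11 were promoter peaks, 5 lay in introns, 1 in another exon and 3 between genes. A nuclear receptor half-site lay at 2 of these 20 summits, a GATA site at 2 and a DR1 at 0. The highest (2L 480838 to 481408, signal 3228) lay in an intron of ush, which encodes a cofactor of GATA factors, 1382 bp from a TSS of cbt, a zinc finger transcription factor gene. It ranked 1, 2 and 3 in replicates 1, 2 and 3. The second (X 2703668 to 2704106, signal 3099) lay 21 bp from a TSS of Ugalt, which encodes a UDP-galactose transporter. The third (3L 19590399 to 19590834, signal 2899) lay 88 bp from a TSS of CG14100. The fourth was at svp itself. The fifth lay in an intron of CG11050 (signal 2865), and the sixth 78 bp from a TSS of PNPase (signal 2639), which encodes the mitochondrial polynucleotide phosphorylase. Promoter peaks with signal values of 2394 and 2367 lay at Chro, a chromodomain protein gene, and larp, an RNA-binding protein gene. One of 2086 lay 153 bp from a TSS of the small heat shock gene Hsp27. Promoter peaks of CG1888, CG18549, CenG1A and CG9147 had signal values from 2161 to 2371. An exon of osa, a Brahma complex gene, held a peak of 2427, and introns of px and of the kinase gene Lk6 held peaks of 2314 and 2278. The remaining peaks were nearest to eEF1gamma, CG13323, CG31668 and CG16753, at distances of 3753 to 11979 bp, the last inside CG32486.

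The svp gene (3R 12258737 to 12302785, plus strand, 44049 bp) carried several of the strongest peaks. From 10000 bp upstream to 10000 bp downstream of it, the IDR-thresholded list had 9 summits, or 1.41 per 10 kb against 0.394 over the arms. The highest (3R 12280746 to 12281313, signal 2869) lay 82 bp from an internal svp TSS and ranked 17, 1 and 7 in replicates 1, 2 and 3. Another promoter peak with a signal value of 1169 (3R 12258808 to 12259643) carried a nuclear receptor half-site at its summit, 356 bp from the nearest svp TSS. Peaks of 1006 and 957 lay in an intron of svp and in an exon of another annotated gene within its bounds. Of the 9 summits, 5 were supported by all 3 replicates. The replicates differed in the number of peaks there. Over the same 64049 bp, the lists of 30000 held 7 peaks in replicate 1, 41 in replicate 2 and 38 in replicate 3, of which 1, 33 and 29 ranked below the top 5000 of their replicate. The density over the arms was 2.18 per 10 kb in each list, and the svp region had 1.09, 6.40 and 5.93. The flies carry the tagged svp as a transgene, per the labels, and whether this adds a further copy of the region is not given in the sources used here.

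**Figure D1:**
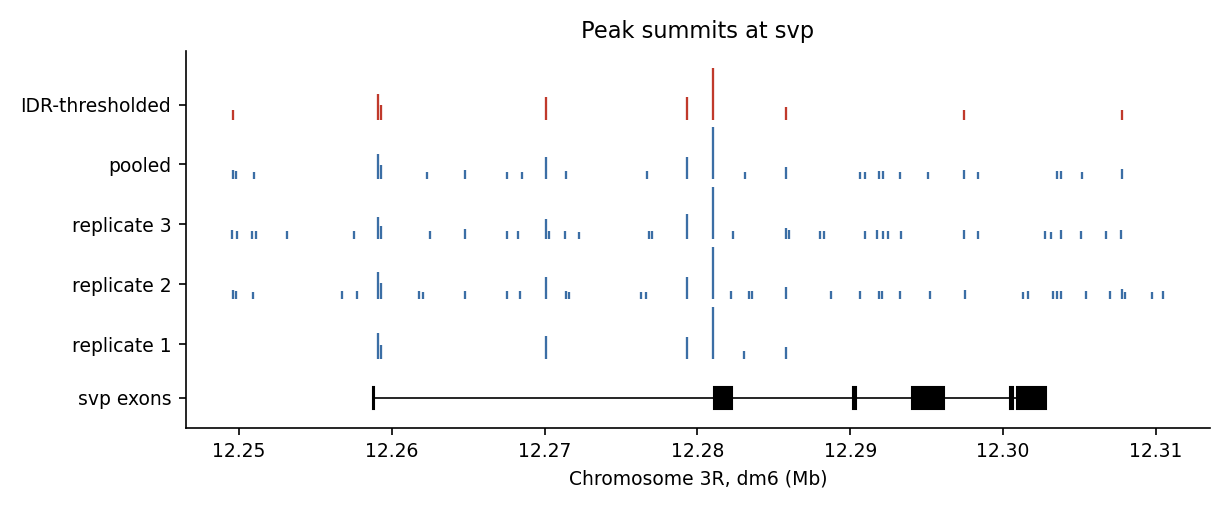
Summits from 10000 bp upstream to 10000 bp downstream of svp on 3R (dm6, Mb), as vertical lines whose height above a short base is the signal value relative to the highest in that list over the region, for the 3 replicate lists, the pooled list and the IDR-thresholded list, with svp exons in black. The highest summit of every list stands at the internal TSS, and replicate 1 has 7 summits in the region where replicates 2 and 3 have 41 and 38.

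The replicates shared most of their strong peaks, and few of the weakest were found in all 3. Among the top 5000 peaks, 70.0% were shared by replicates 1 and 2, 72.6% by 1 and 3, and 76.7% by 2 and 3 (mean 73.1% ± 3.39, SD over 3 pairs). Random placement gave 1.42%, 1.40% and 1.41%, and the permutation p for each pair was 0.001, the smallest possible. The mean falls to 64.7% if at least 50% reciprocal overlap is asked for. Across shared peaks, which are not independent replicates, Spearman's rho of the signal values was 0.739, 0.766 and 0.744. Of peaks ranked 1 to 2500 in a replicate, 86.6% ± 8.69 (SD, n = 3) lay in the lists of both other replicates, against 7.99% ± 0.978 of those ranked 27501 to 30000. Of the latter, 28.0%, 36.0% and 34.2% for replicates 1, 2 and 3 lay in the list of at least 1 other replicate. Of the 5443 IDR-thresholded peaks, 79.6%, 78.0% and 79.8% were in the top 5000 of replicates 1, 2 and 3. All 3 replicates supported 3076 (56.5%, exact 95% interval 55.2 to 57.8), with a median signal value of 306, and 125 were supported by none, with a median of 126. Support by all 3 rose to 84.1% with the top 10000 of each replicate.

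Peak summits lay near promoters far more often than random positions did, and in introns slightly more often. Of 5425 summits on the chromosome arms, 1774 (32.7%, exact 95% interval 31.5 to 34.0) were within 500 bp of a TSS, against 11.5% under random placement (permutation p = 0.001, the smallest possible). Random positions were drawn over the whole length of each arm, with no account of where reads can be mapped. The top 5000 peaks of single replicates gave 34.4% ± 3.97 (SD, n = 3). Introns held 44.3% against 39.9%, and other exons 2.38% against 1.60%. Summits were fewer in intergenic DNA (16.6% against 27.9%), in coding sequence (2.34% against 13.9%) and in 3' UTRs (1.09% against 4.52%), each with a permutation p of 0.001. The share in 5' UTRs outside promoters, 0.627% against 0.793%, did not pass the test (permutation p = 0.187). Of the 1357 summits with the highest signal values 39.4% were at promoters, and of the 1356 with the lowest 29.2%.

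**Figure D2:**
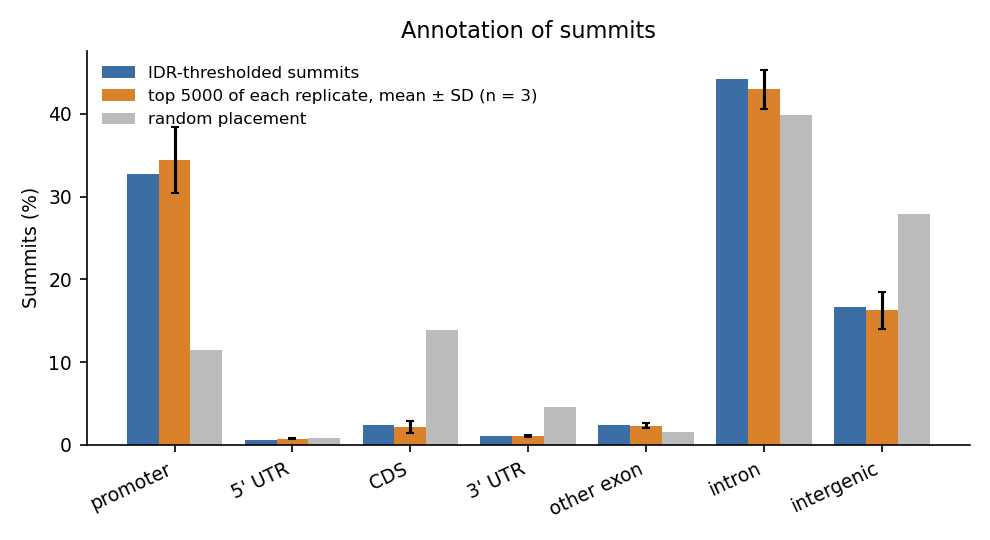
Percent of summits in each annotation class for the IDR-thresholded list (blue), the top 5000 peaks of each replicate (orange, mean ± SD, n = 3) and random placement within chromosomes (grey). Promoters hold 32.7% of the IDR-thresholded summits and 11.5% of random positions, while coding sequence holds 2.34% and 13.9%.

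Chromosome 4, a small and largely heterochromatic chromosome, had almost no peaks. It held 3 summits (0.0553%) against 0.980% expected from its length (two-sided exact binomial test, adjusted p = 1.52e-18). The Y held 0 against 2.67% (exact test adjusted p = 3.08e-63). The full lists of replicates 1, 2 and 3 held 3, 0 and 1 peaks on the Y. Animals of both sexes were used, and the number of Y copies was not taken into account. The expected share of each arm counts its full length, with no account of where reads can be mapped. The test therefore does not show that the tagged protein avoids the Y. The X held 18.8% against 17.1% (exact test adjusted p = 0.00199), and 2L 18.2% against 17.1% (adjusted p = 0.0443). These expected shares count the length of the Y and of chromosome 4, so the near absence of peaks there raises the ratios of the other arms. The X and 2L were not tested against the length of the large arms alone, so their small excess may come from this denominator. The X share was 20.2% in replicate 1 but 16.7% and 17.3% in replicates 2 and 3, and its excess was not past the threshold without replicate 1 (ratio 1.05, exact test adjusted p = 0.276) or in the 50% of peaks with the higher signal values (ratio 1.04, adjusted p = 0.540). Leaving out a replicate, here and below, keeps the IDR-thresholded peaks supported by both others, so both the replicate and the support asked for change. The IDR-thresholded list itself still comes from all 3 replicates, so the replicate left out still contributes to it. This leaves 3611, 3588 and 3463 of the 5425 summits without replicates 1, 2 and 3. Against the share of protein-coding genes, the X ratio rose to 1.20 (exact test adjusted p = 2.55e-09), the 2L ratio changed from 1.07 to 0.959 (exact test adjusted p = 0.151), and 2R changed from 1.03 (adjusted p = 0.445) to 0.926 (adjusted p = 0.0100). The shares of 3L and 3R were 20.4% and 23.5%, with adjusted p of 1 and 0.845.

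Genes of the fat body, the larval organ of lipid storage and secreted proteins, and genes of glycolysis had the highest shares of members with a promoter peak among the 35 lists. Of 13968 protein-coding genes, 2243 (16.1%) had an IDR-thresholded summit within 1000 bp of a TSS. In the fat body and lipid storage list it was 19 of 26 genes (73.1%, odds ratio 13.7, Fisher's exact test adjusted p = 5.54e-09). The replicates gave 71.8% ± 9.68 (SD, n = 3). Random lists matched on gene length and number of TSSs averaged 22.7% (permutation p = 0.0035, adjusted). The highest peaks were at Lpin, a phosphatidate phosphatase gene (signal 1537, 248 bp from a TSS), Apoltp, a lipid transfer particle gene (1260), Mtp, the microsomal triglyceride transfer protein gene (1013), and Fbp2, a fat body protein gene (831). Among the 7 members without a peak were ACC and Agpat1. Of the 19 distinct peaks, 15 were supported by all 3 replicates. In the glycolysis and gluconeogenesis list, 12 of 18 genes had a peak (66.7%, odds ratio 10.1, Fisher's exact test adjusted p = 2.39e-05). The replicates gave 68.5% ± 3.21 (SD, n = 3), and matched lists 25.8% (permutation p = 0.00875, adjusted). The glyceraldehyde-3-phosphate dehydrogenase gene Gapdh2 had a signal value of 1349 and a half-site at its summit. Enolase (Eno) had 901, the hexokinase gene Hex-A 848 and the lactate dehydrogenase gene Ldh 847. G6P and Gapdh1 were among the 6 without a peak.

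Genes of the response to ecdysone, the steroid that starts metamorphosis, carried peaks as well, in a share that random lists of like gene length and TSS number reached at times. The count was 14 of 24 (58.3%, odds ratio 7.26, Fisher's exact test adjusted p = 2.52e-05), and the replicates gave 62.5% ± 4.17 (SD, n = 3). Matched random lists averaged 35.5%, and against them the call was lost (permutation p = 0.128, adjusted). The highest promoter peaks were at the nuclear receptor genes Hr3 (signal 734) and Eip75B (677), at tai, which encodes a coactivator of the ecdysone receptor (564), and at Eip63F-1 (521). Cth and Eip74EF were among the 10 without one, although Eip74EF had 10 summits in its body. Counting the gene body, where a longer gene has a higher chance of a summit, the odds ratio of the list was 24.6 (Fisher's exact test adjusted p = 7.64e-11). Against matched lists, a test chosen after seeing the data, it was 6.03 (87.5% against 50.5%, permutation p = 0.0035, adjusted). The nuclear receptor list, which shares 9 of its 21 genes with the ecdysone list, had 8 with a peak (38.1%, Fisher's exact test adjusted p = 0.0484), among them svp, Hr3, Eip75B and Hr96, whose signal value was 559. ERR and Eip78C were among those without. The odds ratio of 3.30 fell to 1.34 against matched lists, where the call was lost (permutation p = 0.836, adjusted). Without replicate 2 or 3 it was 3.46 and 3.41 on fewer peaks, not past the threshold (exact test adjusted p = 0.102 and 0.0856).

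Insulin and TOR signalling genes had peaks in 10 of 22 cases (45.5%, odds ratio 4.41, Fisher's exact test adjusted p = 0.00559), with the highest at the kinase genes Pi3K92E (signal 471) and Akt (417), the insulin receptor gene InR (316) and the transcription factor gene foxo (250). The insulin-like peptide genes Ilp2 and Ilp3 were among the 12 without. Only 3 of the 10 peaks were supported by all 3 replicates. Without replicate 1, 2 or 3 the odds ratio fell to 2.27, 1.48 and 1.46 and was not past the threshold (exact test adjusted p = 0.367, 1 and 0.943). Against matched lists it was 2.92 (permutation p = 0.0712, adjusted). Chromatin regulator genes had peaks in 10 of 26 cases (38.5%, odds ratio 3.34, Fisher's exact test adjusted p = 0.0217). These were led by the Polycomb gene ph-p (signal 1477), the GAGA factor gene Trl (724), brm (695) and Sin3A (472), while E(bx) and E(z) had none. Without replicate 2 or 3 the odds ratio was 2.62 and 3.13 on fewer peaks, not past the threshold (exact test adjusted p = 0.185 and 0.0834). Against matched lists it fell to 1.90 (permutation p = 0.287, adjusted).

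Chemosensory and cuticle genes had few promoter peaks. None of 119 odorant and gustatory receptor genes had one, Gr10a and Gr10b included (Fisher's exact test adjusted p = 2.52e-08, against 11.8% in matched lists, permutation p = 0.0035, adjusted). All 3 replicates gave 0%. Of 60 ionotropic receptor genes, 1 had a peak, Ir94h (Fisher's exact test adjusted p = 0.00348, permutation p = 0.00875 against matched lists, adjusted), and Ir100a and Ir10a did not. The odds ratio was 0.131, and 0.207 and 0.204 on fewer peaks without replicate 2 or 3, not past the threshold (exact test adjusted p = 0.102 and 0.0622). Of 120 cuticle protein genes, 5 had a peak (4.17%, Fisher's exact test adjusted p = 0.000578), led by Cpr72Eb (signal 324), Cpr49Ac (262) and Cpr62Ba (160). Ccp84Aa and Ccp84Ab had none. Matched lists averaged 9.81%, and against them the call was lost (permutation p = 0.128, adjusted).

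**Figure D3:**
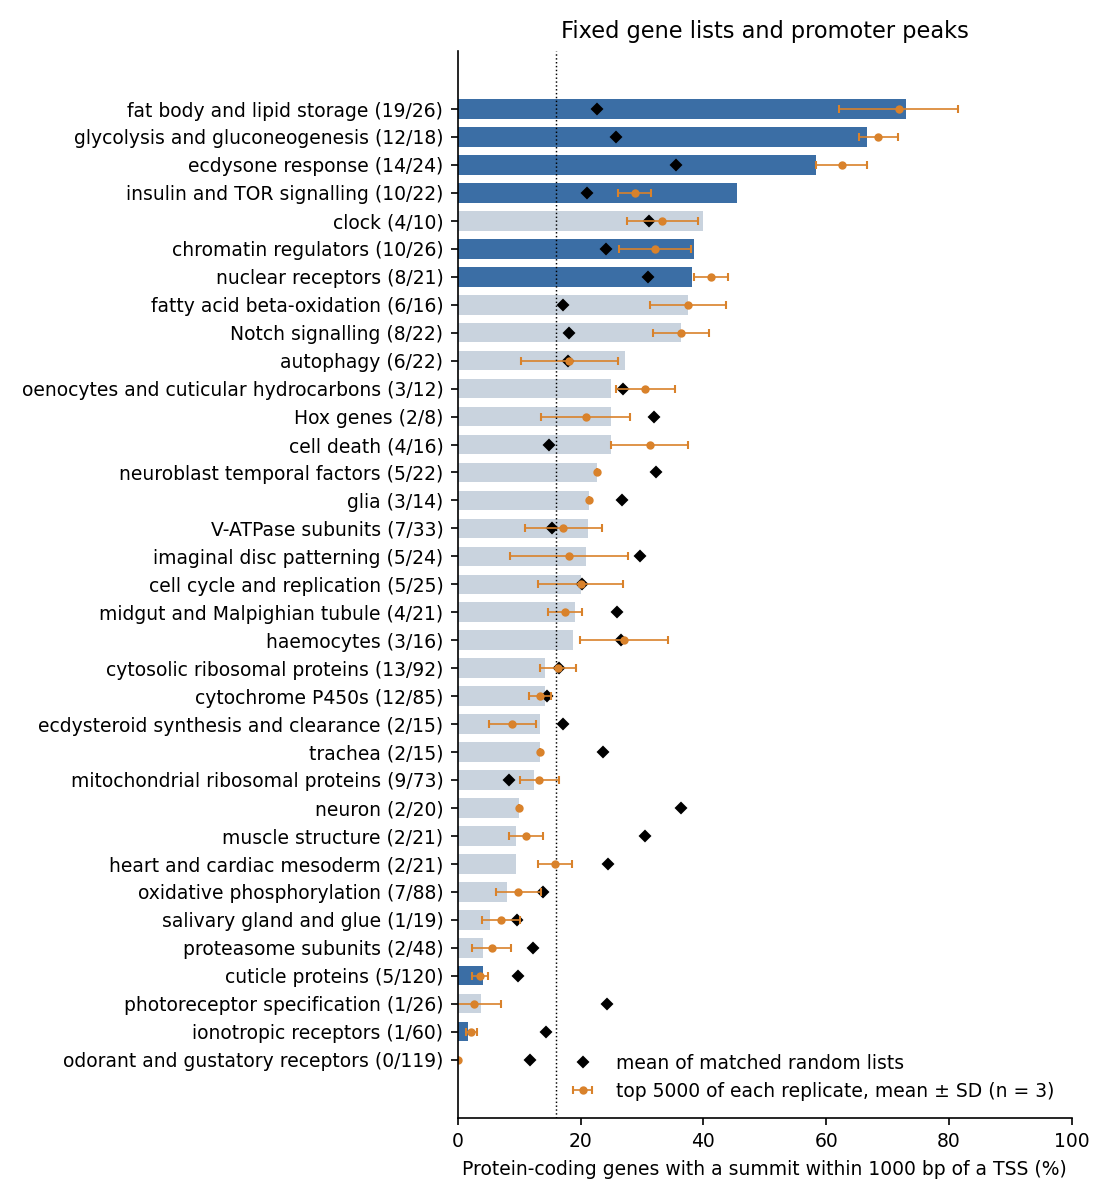
Percent of the genes in each of 35 fixed lists with an IDR-thresholded summit within 1000 bp of a TSS (bars, dark where the adjusted p is under 0.05), the same for the top 5000 peaks of each replicate (orange, mean ± SD, n = 3) and the mean of 10000 random lists matched on gene length and TSS number (diamonds), with counts in brackets and all genes as a dotted line at 16.1%. The fat body list stands at 73.1% and the odorant and gustatory receptor list at 0%.

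The other 26 lists did not pass Fisher's exact test. Above the share of other genes were Notch signalling (8 of 22, exact test adjusted p = 0.0572, led by fng at a signal value of 597 and E(spl)m3-HLH at 541), fatty acid beta-oxidation (6 of 16, adjusted p = 0.0932, led by yip2 at 573 and Mcad at 489) and clock genes (4 of 10, adjusted p = 0.155, led by sgg at 943). Autophagy genes had peaks in 6 of 22 cases, led by Atg2 (464), and cell death genes in 4 of 16, namely hid (953), Dronc (622), Diap1 (517) and egr (211), with adjusted p of 0.327 and 0.636. Peaks were at 5 of 22 neuroblast temporal factor genes (svp, Syp, grh and EcR the highest), 2 of 8 Hox genes (Antp and Abd-B), 5 of 24 imaginal disc patterning genes (brk at 293), 5 of 25 cell cycle and replication genes (stg at 580) and 7 of 33 V-ATPase subunit genes (Vha100-2 at 1280). Their adjusted p ranged from 0.705 to 0.778. Among cell type lists, 3 of 12 oenocyte genes (Hnf4 at 470), 3 of 14 glia genes (moody at 766), 3 of 16 haemocyte genes (Pvr at 493) and 4 of 21 midgut and Malpighian tubule genes (bowl at 776) had peaks, with adjusted p from 0.741 to 0.822. Below the share of other genes were neuron genes (2 of 20, elav and Rbp9, exact test adjusted p = 0.822), muscle structure genes (2 of 21, Msp300 and sls, adjusted p = 0.757), heart and cardiac mesoderm genes (2 of 21, Doc3 and srp, adjusted p = 0.757), trachea genes (2 of 15, grh and trh, adjusted p = 1) and photoreceptor specification genes (1 of 26, so, adjusted p = 0.253). Salivary gland and glue genes had 1 of 19 (CrebA, exact test adjusted p = 0.670), and ecdysteroid synthesis and clearance genes 2 of 15 (Ptth and shd, adjusted p = 1). Cytosolic ribosomal protein genes had 13 of 92 (RpS19b at 531, exact test adjusted p = 0.822), mitochondrial ribosomal protein genes 9 of 73 (mRpS23 at 2165, the peak also nearest to CenG1A, adjusted p = 0.757), proteasome genes 2 of 48 (Rpn8 and Rpn13, adjusted p = 0.0572), oxidative phosphorylation genes 7 of 88 (COX7AL2 at 1295, adjusted p = 0.108) and cytochrome P450 genes 12 of 85 (Cyp6u1 at 588, adjusted p = 0.822).

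Summits carried nuclear receptor half-sites and GATA sites more often than their flanks, and full receptor repeats at few peaks. The half-site RGGTCA lay within 50 bp of 565 of 5425 summits (10.4%) against 279 flanks (5.14%, exact McNemar test, adjusted p = 1.02e-23). The replicates gave 9.93% ± 1.62 at summits and 4.69% ± 0.058 at flanks (SD, n = 3). The GATA site HGATAAR lay at 928 summits (17.1%) against 529 flanks (9.75%, exact McNemar test, adjusted p = 4.45e-29), and the replicates gave 16.7% ± 0.80 and 10.1% ± 0.307 (SD, n = 3). DR1, the direct repeat with a 1 bp spacer bound by COUP-TF receptors, lay at 17 summits against 3 flanks (exact McNemar test, adjusted p = 0.0116), DR3 at 14 against 3 (adjusted p = 0.0458) and DR4 at 17 against 1 (adjusted p = 0.000870). On the fewer peaks without replicate 3 the DR1 excess over flanks was 0.260 percentage points against 0.258 with all, not past the threshold (exact test adjusted p = 0.105). The DR3 excess was 0.222, 0.279 and 0.289 points without replicate 1, 2 or 3 against 0.203, likewise not past it (exact test adjusted p = 0.193, 0.0645 and 0.0766). The reversed DR1 lay at 2 summits and 6 flanks (exact test adjusted p = 0.473). Without replicate 1 or 3 this control passed as less frequent at summits (1 against 10 and 0 against 9, exact test adjusted p = 0.0422 and 0.0188). The test against flanks can thus call its own control at counts as small as those of the repeats. None of the remaining 12 motifs passed the test. DR0 (15 against 5) and DR2 (17 against 6) had adjusted p of 0.105 and 0.104, DR5 (11 against 4) 0.213 and IR1 (4 against 1) 0.563. Summit counts of the direct repeats ranged only from 11 (DR5) to 17 (DR1, DR2 and DR4). Spacers were not tested against each other, so a preference for DR1 is not shown. A repeat with 1 mismatch still holds an exact half-site, so these counts are not independent of the half-site count. The extended half-site (17 against 18), GAGA (125 against 117), DRE (22 against 18), M1BP (15 against 10), E-box (46 against 68), Zelda (20 against 33), AP-1 (53 against 62) and initiator (570 against 547) had adjusted p from 0.105 to 1. Against windows matched on annotation and GC content, GAGA (2.30% against 1.03%, exact test adjusted p = 1.61e-06) and DR2 (17 against 2, adjusted p = 0.00262) passed as well. Within 100 bp of the summit DR0 and DR2 passed against the flank (exact test adjusted p = 0.0180 and 0.0255). By distance, GAGA had 1.08 sites per kb from -125 to -101 bp of the summit and 1.02 from 125 to 149 bp. It had 0.487 from 0 to 24 bp and 0.538 from 500 to 524 bp, and this profile was not tested. GC content was 38.8% at summits and 42.8% at flanks.

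**Figure D4:**
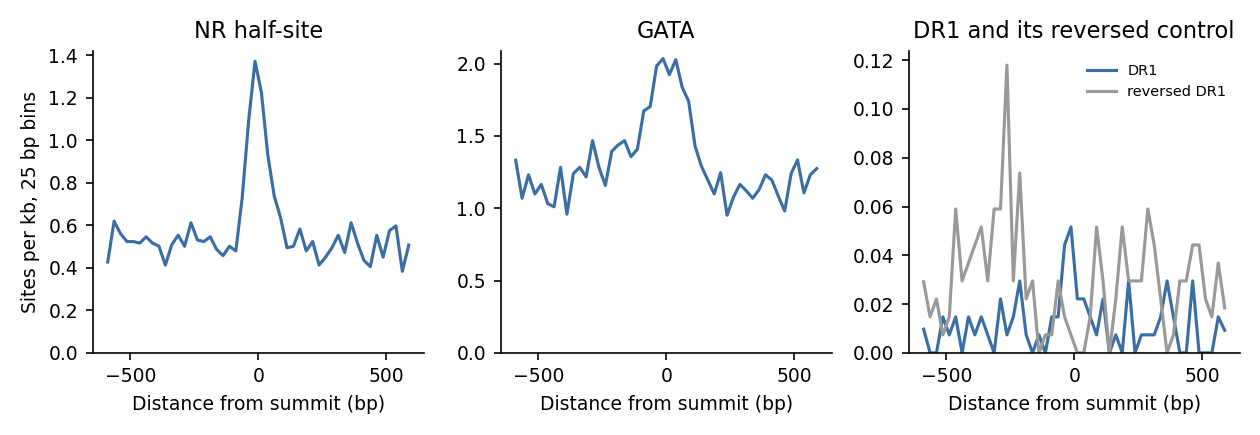
Sites per kb in 25 bp bins by distance from the IDR-thresholded summit (bp) for the nuclear receptor half-site, the GATA site, and DR1 with its reversed control, each panel on its own scale starting at 0. The half-site reaches 1.37 sites per kb in the bin just before the summit and GATA 2.04.

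A search over 32891 8-mers without fixed motifs gave GATA-containing words first. A total of 208 were more frequent at summits and 62 less frequent. Flanks had the higher GC content (42.8% against 38.8%), and 8-mers were not tested against windows matched on it. How far base composition accounts for these counts was therefore not tested. The smallest adjusted p was that of GATAACCC, at 60 summits against 3 flanks (exact McNemar test, adjusted p = 2.98e-10). AGGTTATC followed (60 against 5, exact test adjusted p = 8.01e-09), then TTTAAAAA (244 against 118), CTGATAAG (112 against 33) and GCTTATCA (97 against 25). Read on either strand, GATAACCC and AGGTTATC hold GATAAC, which does not match the tested site HGATAAR. They also hold RGGTTA, which differs from the half-site RGGTCA by 1 base. CTGATAAG and GCTTATCA do match HGATAAR. CAACAACA (85 against 191) and AACAACAA (114 against 233) were less frequent. CTTTAAAA (120 against 40), TCTTAAAA (95 against 27) and ATTTTAAA (217 against 107) completed the first 10. Their adjusted p after the second word ranged from 1.81e-07 to 2.83e-06. In the 50% of peaks with the higher signal values 43 words were more and 9 less frequent, and 5 of its first 10 were shared.

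The genes with the most summits in their body were kirre, sbb, ush, shn and Eip75B. The kirre gene, which encodes an immunoglobulin-domain protein of myoblast fusion, had 21 in 394149 bp (0.533 per 10 kb). The transcriptional regulator genes sbb and ush had 18 each (2.28 and 2.80 per 10 kb), the zinc finger gene shn 17 (2.92 per 10 kb) and Eip75B 16 (1.41 per 10 kb). Mnt also had 16, tied with Eip75B and listed after it by name, so it was chosen after its values were seen. In the 50% of peaks with the higher signal values, kirre (14), ush (13) and shn (11) again had the most, and sbb had 10, tied with CG1677 and CHES-1-like, 2 genes that were chosen after their values were seen.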

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

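Peaks on the mitochondrial genome were left out of the arm, motif and gene analyses above, while replicate overlap and support counted them. The IDR-thresholded list on dm6 holds 18 such peaks. Their median signal value was 633 against 218 for the peaks on the arms, and they covered 5804 of 19524 bp. The top 5000 peaks of replicates 1, 2 and 3 supported 1, 15 and 16 of them, and the dm3 list had 0 there.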

How the results depend on the processing

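Most results kept their direction and their side of the threshold. Of 536 values recomputed for single arms, motifs and lists, 385 kept both, 93 reached or crossed their null value but were past the threshold in neither setting, 40 lost the threshold, 16 gained it and 2 reversed. The promoter share stayed above random placement in every setting, from 22.7% within 250 bp of a TSS to 43.6% within 1000 bp. The fat body and glycolysis calls held in all alternatives run, and the half-site and GATA calls likewise. The 2 reversals came with the share of protein-coding genes as the expectation, where the ratio was 0.959 for 2L and 0.926 for 2R; the cause was not tested. The mean replicate overlap was 64.7% with at least 50% reciprocal overlap, 67.7% with summits within 100 bp, 66.9% with the top 10000, and 70.0% to 76.7% without 1 replicate. Support of the IDR-thresholded peaks was 84.1% with the top 10000, 51.5% with summits within 100 bp, 47.1% on dm3, where the list is longer, and 63.6% to 66.6% without 1 replicate, where support by fewer lists is asked for. Motifs more frequent at summits numbered 3 in place of 5 in the 50% of peaks with the higher signal values and in windows of 25 bp to each side, 3 to 4 without 1 replicate, and 7 against matched windows and in windows of 100 bp to each side. Those less frequent numbered 1 in place of 0 in windows of 100 bp to each side (Zelda), and 0 to 1 without 1 replicate, where the reversed DR1 control passed without replicate 1 or 3. The 8-mers fell from 208 to 43 and from 62 to 9 in the 50% of peaks with the higher signal values, which are fewer. Lists with peaks more often numbered 3 in place of 6 in the same 50% of peaks and among peaks supported by all 3 replicates, 2 against matched lists, 4 within 5000 bp of a TSS, 7 within 500 bp, 8 when the gene body was counted, and 3 to 6 without 1 replicate. Counting the gene body, Notch signalling and imaginal disc patterning passed (odds ratios 3.98 and 4.68, exact test adjusted p = 0.00526 and 0.000991), as did fatty acid beta-oxidation within 500 bp (0.0402) and haemocytes within 5000 bp (0.0277). Without replicate 1, Notch signalling passed (odds ratio 3.49, exact test adjusted p = 0.0499) while insulin did not. Against matched lists the gene body, a setting chosen after seeing the data, gave 3 (ecdysone, fat body and glycolysis) and 2 less often. The nuclear receptor, insulin and chromatin calls were lost within 5000 bp of a TSS (odds ratios 2.63, 2.38 and 2.32, exact test adjusted p = 0.122 for each). These calls and that of the ionotropic receptors were lost in the peaks with higher signal values and in those supported by all 3 replicates. In these 2 settings, which hold 2706 and 3076 of 5425 summits, the odds ratio was 3.75 and 3.77 for nuclear receptors, 3.44 and 2.85 for chromatin and 2.17 and 1.61 for insulin, against 3.30, 3.34 and 4.41. For ionotropic receptors it was 0.224 and 0.225, against 0.131. The DR1 and DR3 calls were lost in the windows of 25 bp (exact test adjusted p = 0.535 and 0.680), and the DR3 and DR4 calls in the fewer peaks with higher signal values (exact test adjusted p = 0.0582 and 0.0773), where the excess was 0.370 and 0.296 points against 0.203 and 0.295. DR3 was also lost among peaks supported by all 3 replicates (0.325 points, exact test adjusted p = 0.0547). Lists with peaks less often numbered 5 in place of 3 when the gene body was counted, where oxidative phosphorylation and the proteasome passed (exact test adjusted p = 0.00874 and 0.00875). They numbered 4 within 500 bp (oxidative phosphorylation gained, 0.0242) and within 5000 bp (salivary gland and glue gained, 0.0287). They numbered 2 in the same 50% of peaks, among peaks supported by all 3 replicates and against matched lists, and 2 to 3 without 1 replicate. For the other changes the cause was not tested. The planned dm3 alternatives for the arm shares and the svp locus were not run, since no dm3 lengths or gene positions were used here. Unknown read depth limits what a missing peak shows, so the genes without a peak are not shown to be unbound.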

Other observations

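Gene families grouped by symbol, a grouping chosen after the data were seen, add a few contrasts. Of 78 families with at least 10 members, the histone genes had the smallest p, with a promoter peak at 1 member (0.870%, Fisher's exact test adjusted p = 4.78e-06). Most histone genes lie in a tandem array of near-identical copies, and how reads shared between copies were placed is not given in the sources used here. The Or, Gr and Ir families followed. Tetraspanin genes (12 of 35, 34.3%) had the smallest p among families with more peaks and did not pass (exact test adjusted p = 0.129). Peaks on chromosome 4 numbered 10, 63 and 145 in the lists of 30000 of replicates 1, 2 and 3. Promoter summits carried the DRE site at 1.07% against 0.0822% of other summits (Fisher's exact test adjusted p = 5.14e-06), and GAGA at 3.21% against 1.86% (adjusted p = 0.0238). Their flanks carried DRE at 0.620% against 0.192% and GAGA at 1.47% against 2.49%.

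The matched lists and the wider windows were planned before the data were examined and were set against these explanations after their values were seen. The tests of transcription, tissue and tiles, and of single lists for sites, were chosen only after the results were seen. The tests of GATA with half-sites and of GATA at both lists' peaks were chosen before their own values were seen, but after the motif and list results, which gave the site and the 2 lists. No biological explanation was tested against another group, since there is 1 group.

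Promoter peaks at fat body and glycolysis genes were more frequent than gene length and number of TSSs give. The adjusted permutation p against matched lists was 0.0035 for the fat body list and 0.00875 for the glycolysis list. For the ecdysone list it was 0.128, with 58.3% against 35.5%, so for its promoter peaks length and TSS number cannot be told apart from the rest. Of the cytosolic ribosomal protein genes, taken as strongly transcribed, 14.1% had a promoter peak (exact 95% interval 7.74 to 23.0). This argues against peaks at strongly transcribed genes of every kind. It rests on 1 gene family without expression values, so a part of transcription at other genes is not excluded. Open promoters of every tissue alike were argued against by the muscle structure genes, with 9.52% (1.17 to 30.4). It stays open whether the peaks mark svp binding or open chromatin taken up by any antibody, since no GFP-free sample is used here. The chromatin came from whole animals, so the organs in which these peaks arose are not known.

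Weak peaks, those below the top 5000 of their replicate, lay across the svp region in replicates 2 and 3 (33 and 29) but hardly in replicate 1, a split that was rare over equal tiles of the arms. Of 2142 other tiles of 64049 bp, 1 had as high a ratio of weak peaks in replicates 2 and 3 to replicate 1, and 31 (1.45%) as high a ratio of all peaks. In 6 tiles replicates 2 and 3 both had as many weak peaks, and in 0 of these replicate 1 had as few. Replicate 1 was also the lowest on the mitochondrial genome (1, 27 and 24 peaks) and on chromosome 4 (10, 63 and 145), so a general difference between the libraries cannot be told apart from one at svp. A further copy of the svp region in the tagged flies of all 3 replicates may add weak peaks, but replicate 1 had 1 there against a tile median of 10, and 11.95% of tiles had as few, which does not decide it. A copy number that differs between replicates stays open, as no reads are used here.

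Receptor repeats were at few summits, half-sites at 10.4% and GATA sites at 17.1%, and 25.1% carried either of these 2. Imprecise summit positions were argued against, since windows of 100 bp to each side had a DR1 at 0.424% of summits. If GATA sites stood in for half-sites, GATA would be rarer at summits with a half-site. It was more frequent there (22.8% against 16.4%, odds ratio 1.504, 95% interval 1.21 to 1.86, Fisher's exact test adjusted p = 0.000726), which argues against replacement over the summits as a whole. Replacement at part of the summits is not excluded, since signal, GC content and promoter class were not held equal in this test. Half-sites and GATA sites that differ from the consensus at any base, and repeats that differ by more than 1 base, were not counted and stay open.

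A further hypothesis was that sites of GATA factors, among them the fat body factor gene srp, mark the fat body and glycolysis promoter peaks. A GATA site lay at 12 of the 31 such peaks (38.7%) against 17.0% of other peaks (odds ratio 3.09, 95% interval 1.36 to 6.72, Fisher's exact test adjusted p = 0.00343). A half-site lay at 9 of the 31 (29.0%) against 10.3% (odds ratio 3.56, 95% interval 1.43 to 8.09, exact test adjusted p = 0.00343), a test added beside it. By list, GATA passed at the fat body peaks (9 of 19, odds ratio 4.39, exact test adjusted p = 0.00868) and not at the glycolysis peaks (3 of 12, odds ratio 1.62, adjusted p = 0.443). Half-sites passed at the glycolysis peaks (5 of 12, odds ratio 6.19, exact test adjusted p = 0.0102) and not at the fat body peaks (4 of 19, odds ratio 2.30, adjusted p = 0.171). The pooled GATA value met the prediction for both lists together, while by list GATA passed at the fat body peaks only. Whether the lists differ was not tested.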
